A study of Caenorhabditis elegans with 12 samples.

How the data were processed

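Total RNA of 12 samples of wild-type (N2) Caenorhabditis elegans was measured on Affymetrix 3' expression arrays with biotin label, 3 arrays for each of 4 RNAi groups: empty vector, hsp-6, hsp-6 with hsf-1, and hsp-6 with dve-1. Per the labels, synchronized worms were day 3 adults after 3 days on RNAi bacteria, and eggs and larvae were washed off during that time. The deposited values are log2 GCRMA values, in which the authors corrected background, normalized the arrays and summarised each probe set. The submitters' notes name GCOS 1.4 and GCRMA, and the GCRMA settings and version are not given in the sources used here. The values ran from a shared minimum of 2.16, and array medians over the tested probe sets ran from 7.94 to 8.11. Changes measured against that minimum are lower bounds. No raw intensities were used here. Arrays carry no count depth, so the number of arrays limits the precision.

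Probe sets were named from the array's annotation table. Of 22625 probe sets, 20766 carried 1 gene symbol, 887 several, 895 none, and 77 were controls. Probe sets with several symbols were counted but not named. A RefSeq table was used to check gene names, and 20701 probe sets with 1 symbol were found in it; no positions are given, since the sources used here give none for the probes. Control probe sets were left out, and probe sets were tested when their log2 value was above 4 in at least 3 of the 12 arrays, which left 12057, standing for 9172 genes with a symbol of their own.

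Groups were compared with limma 3.58.1 in R 4.3.3, in 1 fit of 4 group means to all 12 arrays, with the intensity trend in the variance model (8 residual and 3.16 prior degrees of freedom). A probe set was called at a Benjamini-Hochberg adjusted p below 0.05 over the probe sets tested, separately in each comparison, and tests were two-sided. hsp-6 RNAi was compared with empty vector, and both double RNAi groups with hsp-6 RNAi, with each other and with empty vector. The covariances of changes in comparisons that share the hsp-6 RNAi arrays, and the overlaps of their calls, were set beside 100 simulations. In these the groups share arrays as here, no gene differs, and the noise is independent for each probe set and array. A further 100 kept the measured hsp-6 RNAi change and gave the added RNAi no effect. Arrays were compared by principal components over the tested probe sets. Replicate numbers were not taken to pair samples, since the labels do not say so.

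35 gene lists of stress responses, lipid and energy metabolism, protein synthesis, defence, and tissue or germline markers were tested with camera, with a preset correlation of 0.01 between genes and again with a correlation estimated per list, and with fry. A gene with several probe sets was represented by the one with the highest mean. Counts adjusted over the list alone use Benjamini-Hochberg within the list. 3 further lists, of moulting, intracellular pathogen response and male soma genes, were written after the data had been seen. The comparisons, the test, the filter, the 35 lists, the alternatives and the rule for named genes were set before the data were examined.

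Genes named are the RNAi targets, and per comparison the 8 largest called rises and falls among probe sets with 1 symbol and no overlap between the arrays of the groups. They also include the 3 largest called members of each list, the 8 largest hsp-6 RNAi changes in each overlap, and hsp-60, hsp-70, the hsp-16 genes, fasn-1 and pod-2 whatever their result. The text names fewer, in the order of that rule, and other list members named were chosen after their values were seen. Values given with a gene are the log2 difference, its standard error (SE) and its adjusted p, all from limma.

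The calls were tested on simulated data with the same groups and spread, with 200 changed probe sets in each of 20 simulations. Changes of 1 on the log2 scale were recovered in 24.8%, 25.4% and 24.4% of cases, and changes of 2 in 81.0%, 80.2% and 79.8%. The order is hsp-6 RNAi against empty vector, then the hsf-1 double RNAi group and the arrays labelled hsp-6;dve-1 against hsp-6 RNAi. Of the probe sets called in the simulations, 5.1%, 4.8% and 4.9% were false. The noise was drawn independently for each probe set and array, while the real arrays vary together over many probe sets. These shares therefore need not hold for the calls given here. The alternatives were no filter, a minimum of log2 6, another quantile normalization, centring on array medians, the variance model without trend or with robust fitting, low values set to log2 4, a fit of the compared groups alone, the replicate number as a block, and leaving out each array in turn. Added after the data had been seen were the average of hsp-6 RNAi replicates 1 and 3, the most alike arrays and possibly repeats of 1 culture, used as 1 array, and a fit without the 2 arrays farthest out on the first principal component. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.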

Results

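The data are 12 Affymetrix expression arrays of whole wild-type (N2) Caenorhabditis elegans, in 4 groups of 3 arrays. Worms were fed bacteria carrying an RNA interference (RNAi) vector from day 1 of adulthood for 3 days. The vector was empty in the control group, and targeted hsp-6, hsp-6 with hsf-1, or hsp-6 with dve-1 in the others. hsp-6 encodes the mitochondrial Hsp70 chaperone, hsf-1 the transcription factor of the heat shock response, and dve-1 a homeodomain protein of the mitochondrial unfolded protein response. The design asks which genes respond to loss of hsp-6, and which of these responses need hsf-1, dve-1 or both. Between 49.01% and 52.91% of each array's probe sets lay above log2 4, and 12057 of 22625 probe sets were tested; the number of arrays limits the precision. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these samples. hsp-6 RNAi replicates 1 and 3 were the most alike of all arrays, and if they repeat 1 culture, that group holds 2 samples rather than 3. With these 2 arrays averaged into 1, a choice made after seeing the data, the totals of called probe sets fell. The total for hsp-6 RNAi against empty vector went from 330 to 102. Against hsp-6 RNAi, the hsf-1 double RNAi group went from 684 to 35, and the arrays labelled hsp-6;dve-1 from 692 to 106.

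The hsp-6 transcript averaged 11.12 ± 0.17 on the log2 scale with empty vector and 6.84 ± 0.21 with hsp-6 RNAi (mean ± SD, n = 3 each). It averaged 9.63 ± 0.41 with hsp-6 and hsf-1 RNAi and 9.82 ± 0.60 in the arrays labelled hsp-6;dve-1. The hsp-6 transcript was thus less reduced in both double RNAi groups, where it lay 2.79 (SE 0.30, adjusted p = 0.0024) and 2.98 (SE 0.30, adjusted p = 0.00086) above hsp-6 RNAi alone. A further hsp-6 probe set was higher by 1.99 (adjusted p = 0.023) and 2.25 (adjusted p = 0.014). Whether hsp-6 RNAi bacteria were diluted alike in the group with hsp-6 RNAi alone is not given in the sources used here, so a difference in dose is not separated from the added RNAi. hsf-1 averaged 6.92 ± 0.29 with hsp-6 and hsf-1 RNAi against 7.82 ± 0.17 with hsp-6 RNAi, a difference of -0.90 (SE 0.32, adjusted p = 0.12). With empty vector hsf-1 read 8.63, 8.26 and 8.8, above the 7.94, 7.63 and 7.9 of the hsp-6 RNAi arrays. The other hsf-1 probe set read 8.66, 7.64 and 8.45 with empty vector and 7.52, 7.28 and 7.49 with hsp-6 RNAi. It read 6.78, 7.09 and 6.08 with hsp-6 and hsf-1 RNAi. dve-1 went against its label: it averaged 8.06 ± 0.88 in the arrays labelled hsp-6;dve-1 and 5.53 ± 0.39 with hsp-6 RNAi, a rise of 2.53 (SE 0.57, adjusted p = 0.03). It also read 8.18 in hsf-1 double RNAi replicate 3, above 2 of the 3 arrays labelled hsp-6;dve-1. The other dve-1 probe set differed by 0.24 (adjusted p = 0.63). hsf-1 read 6.68 to 7.24 in the hsf-1 double RNAi arrays, and 8.12 and 8.04 in hsp-6;dve-1 replicates 1 and 3 but 6.87 in replicate 2. As labelled, the double RNAi groups differed in 28 probe sets. With hsf-1 double RNAi replicate 3 and hsp-6;dve-1 replicate 2 exchanged they differed in 0. With replicate 2 of each group exchanged they differed in 687. These values do not settle whether the first probe set also detects RNA of the RNAi construct or whether labels were exchanged, so they do not show whether dve-1 was knocked down. The call on dve-1 was lost without hsp-6 RNAi replicate 1, 2 or 3, or hsp-6;dve-1 replicate 1 or 2, with adjusted p up to 0.11.

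**Figure D1:**
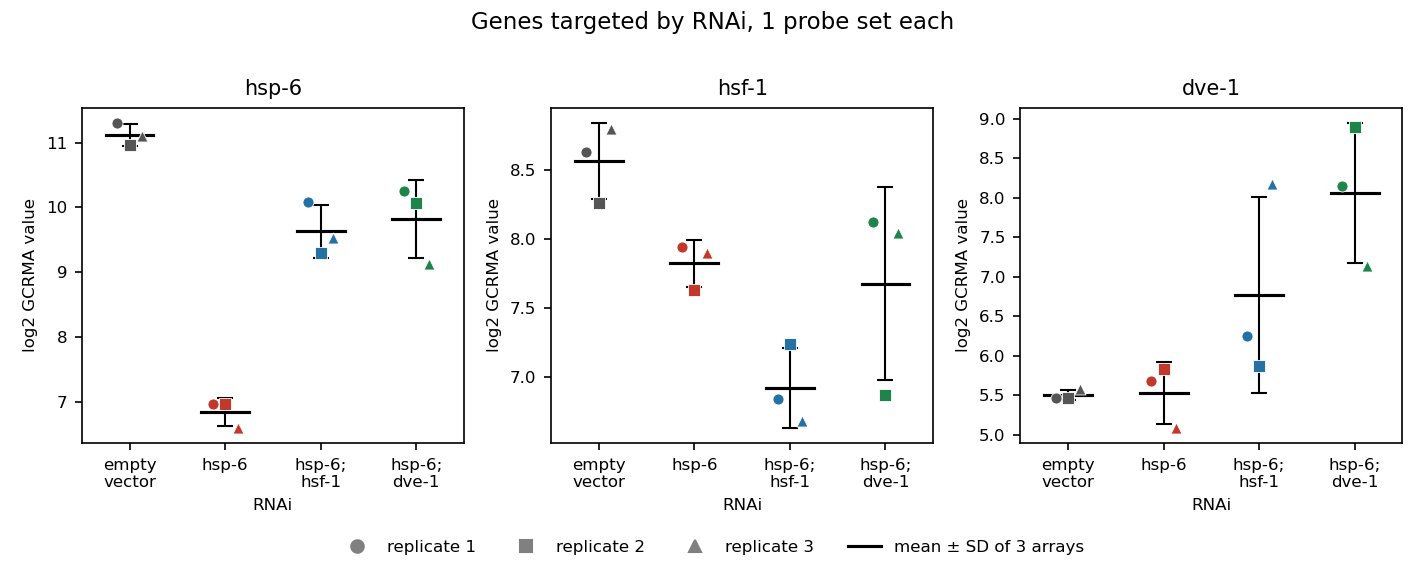
Log2 GCRMA value (vertical axis) of hsp-6, hsf-1 and dve-1 in the 4 RNAi groups (horizontal axis), with 1 point per array and lines for the mean ± SD of 3 arrays. hsp-6 falls to 6.84 with hsp-6 RNAi alone and lies at 9.63 and 9.82 in the double RNAi groups, and dve-1 is highest, at 8.06, in the arrays labelled hsp-6;dve-1.

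Loss of hsp-6 raised 4 cytosolic heat shock genes by 21.7-fold or more, and 3 of them were among the 8 largest rises of genes with their own symbol. hsp-70, a heat-inducible cytosolic chaperone, rose from 6.47 ± 0.50 to 12.92 ± 0.27, a log2 change of 6.46 (SE 0.57, 87.7-fold, n = 3, adjusted p = 0.00056). The small heat shock genes hsp-16.41 and hsp-16.2 rose by 5.72 (SE 0.71, adjusted p = 0.0027) and 5.63 (SE 0.75, adjusted p = 0.0037), and hsp-17 rose by 4.44 (SE 0.75, adjusted p = 0.011). hsp-60, the mitochondrial chaperonin, went the other way, with a fall of 1.53 (log2 change -1.53, SE 0.31, adjusted p = 0.027). Single sugar-processing enzymes rose as well: aldolase aldo-1 by 3.47 (SE 0.33, adjusted p = 6e-04) and lactate dehydrogenase ldh-1 by 2.41 (SE 0.35, adjusted p = 0.0053). The calls on hsp-70, hsp-16.41, hsp-16.2, aldo-1 and ldh-1 held without any 1 of the 12 arrays. That on hsp-17 was lost without hsp-6 RNAi replicate 1 or 3 (adjusted p up to 0.059), and that on hsp-60 without empty vector replicate 1, 2 or 3 or hsp-6 RNAi replicate 1 or 2 (up to 0.11).

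**Figure D2:**
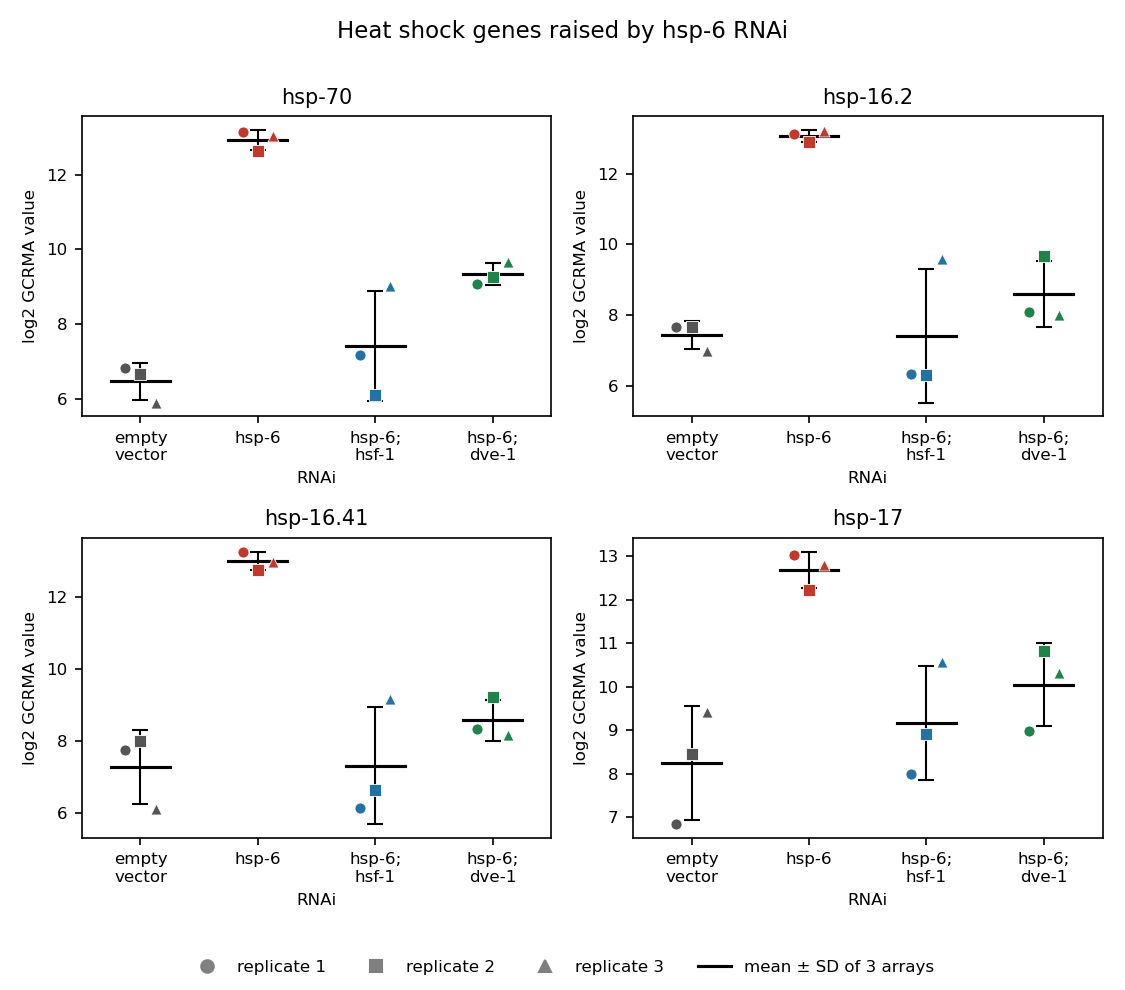
Log2 GCRMA value (vertical axis) of hsp-70, hsp-16.2, hsp-16.41 and hsp-17 in the 4 RNAi groups (horizontal axis), with 1 point per array and lines for the mean ± SD of 3 arrays. hsp-70 rises from 6.47 with empty vector to 12.92 with hsp-6 RNAi and lies at 7.42 and 9.33 in the double RNAi groups.

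Of the 23 tested genes of the cytosolic heat shock list, 4 rose with hsp-6 RNAi and none fell, and 4 rose adjusted over the list alone. Their median change was 0.24, and the list was called higher by camera (adjusted p = 0.0157; adjusted p = 0.396 with an estimated correlation), a call lost without empty vector replicate 2 (0.0566). Of 13 genes of the mitochondrial unfolded protein response list, which leaves out hsp-6, 2 rose and 1 fell, and the list was not called (adjusted p = 0.0874, median 0.27). The members that rose were hrg-9, by 4.49 (adjusted p = 0.0062), and gpd-2, a glycolytic enzyme, by 0.72 (adjusted p = 0.028), while the chaperonin hsp-60 fell. No member of the lists for cytosolic chaperonin and prefoldin (14 genes, adjusted p = 0.765) and the endoplasmic reticulum unfolded protein response (20 genes, adjusted p = 0.159) passed the test. Glycolysis genes were called higher with 3 of 17 up (4 up and 1 down adjusted over the list alone, median 0.23, adjusted p = 0.0157). With an estimated correlation the glycolysis list gave adjusted p = 0.396, and without empty vector replicate 2 it gave 0.0663.

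Lists of genes for making proteins and for respiration were called lower with hsp-6 RNAi, though few of their members passed and no list held with an estimated correlation. Mitochondrial ribosomal protein genes fell as a list, with 7 of 57 down and none up (16 down adjusted over the list alone, median -0.36, adjusted p = 4.53e-07, and adjusted p = 0.606 with an estimated correlation). The largest falls were in mrps-21 (-1.52, SE 0.23, adjusted p = 0.0074), mrpl-12 (-1.47, adjusted p = 0.024) and mrps-25 (-1.35, adjusted p = 0.02). Cytosolic ribosomal protein genes moved little but together, with 1 of 61 down, 17 down adjusted over the list alone, a median of -0.16 and adjusted p = 3.42e-11 (adjusted p = 0.606 with an estimated correlation). For the proteasome, 1 of 33 fell, rpn-6.2 by 1.08 (log2 change -1.08), with a list adjusted p = 0.00167 that became 0.828 with an estimated correlation and 0.0552 without hsp-6 RNAi replicate 2. The respiratory chain list had 2 of 67 down, including atp-1 (-0.80), and cytochrome c gene cyc-2.1 up by 0.42. Its adjusted p = 0.00167 (median -0.20) became an adjusted p = 0.606 with an estimated correlation and 0.095 without empty vector replicate 3. Adjusted over the list alone, 1 proteasome gene fell, and in the respiratory chain 1 rose and 2 fell. The lists for mitochondrial import (18 genes, adjusted p = 0.388) and the tricarboxylic acid cycle (21 genes, adjusted p = 0.151) had no member past the threshold.

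Among lipid genes, fat-5, a palmitoyl-CoA desaturase, rose by 1.41 (SE 0.24, adjusted p = 0.012), and no other gene of the 20 for fatty acid synthesis and desaturation passed the test (3 up and 1 down adjusted over the list alone, list adjusted p = 0.143). Fatty acid synthase fasn-1 differed by -0.89 (SE 0.29, adjusted p = 0.11) and acetyl-CoA carboxylase pod-2 by 0.04 (SE 0.28, adjusted p = 0.97). Of 18 lipid-binding and lipid droplet genes, dhs-9 rose by 1.22 and far-1 by 0.70, with 5 up adjusted over the list alone. That list was called higher (median 0.31, adjusted p = 0.0157; adjusted p = 0.606 with an estimated correlation), but not without empty vector replicate 1 (0.0943). Sphingosine kinase sphk-1 fell by 0.91 (log2 change -0.91, adjusted p = 0.044), and was the 1 of 19 sphingolipid genes past the threshold (list adjusted p = 0.681). None of the 38 genes for fatty acid oxidation and lipases (list adjusted p = 0.784, median -0.08, mean 0.04), the 24 for phospholipid synthesis (0.765) or the 5 yolk genes (0.782, median 0.05, mean -0.19) passed the test.

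Some detoxification, antimicrobial and nuclear receptor genes rose with hsp-6 RNAi, a minority of each list. Of 42 UDP-glucuronosyltransferases 2 rose (3 adjusted over the list alone), ugt-1 by 3.17 (SE 0.39, adjusted p = 0.0026) and ugt-27 by 2.24, with list adjusted p = 0.00167 and median 0.58. Of 41 cytochrome P450 genes 3 rose (3 adjusted over the list alone), led by cyp-36A1 at 3.63, with list adjusted p = 0.00199 and median 0.62. gst-22 rose by 1.46 among 30 glutathione transferases (5 up adjusted over the list alone), with list adjusted p = 0.00493 that was 0.113 without empty vector replicate 1. Of 52 lysozyme, saposin-like and antimicrobial peptide genes 5 rose (11 adjusted over the list alone, median 0.72, adjusted p = 1.35e-05), among them cnc-4 by 1.85 (adjusted p = 0.0076) and spp-24 by 1.62 (adjusted p = 0.006). Of 108 nuclear hormone receptor genes 5 rose (5 adjusted over the list alone, median 0.38, list adjusted p = 0.00167), with nhr-132 at 3.60 (adjusted p = 0.0047). These 5 lists gave adjusted p = 0.606 with an estimated correlation. Mitochondrial superoxide dismutase sod-3 rose by 1.38 (adjusted p = 0.036), 1 of 13 in its list and 1 adjusted over the list alone. The list's adjusted p was 0.0346, or adjusted p = 0.396 with an estimated correlation, and it rose to 0.0631 without empty vector replicate 2 and 0.0547 without hsp-6 RNAi replicate 3. Of 61 C-type lectin genes 2 rose (3 adjusted over the list alone, adjusted p = 0.0382, and adjusted p = 0.828 with an estimated correlation). The lectin call was lost without empty vector replicate 1 (0.134) or hsp-6 RNAi replicate 2 (0.0702).

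Few markers of tissues and of the germline passed with hsp-6 RNAi. Of 103 cuticle collagen genes 2 rose and 2 fell, the same counts adjusted over the list alone, and the list was lower (median -0.39, adjusted p = 0.00201). This became adjusted p = 0.836 with an estimated correlation and 0.0886 without empty vector replicate 2. rol-6 rose by 3.77 (adjusted p = 0.048) and col-20 fell by 2.08 (log2 change -2.08, adjusted p = 0.0039). Of 33 germline genes 1 fell (3 adjusted over the list alone), fbf-2 at -1.77 (adjusted p = 0.049), with list adjusted p = 0.00201 and adjusted p = 0.828 with an estimated correlation. The 10 embryo markers had a median of -0.98 (1 down adjusted over the list alone, adjusted p = 0.0147). Their adjusted p = 0.606 with an estimated correlation, and it was 0.0551 without hsp-6 RNAi replicate 2. The intestinal ferritin gene ftn-1 rose by 2.54, 1 of 20 intestine markers (list adjusted p = 0.681). Sperm (49 genes, 0.371), oocyte (23, 0.765), histone (25, 0.136), muscle (20, 0.582), neuron (32, 0.225), hypodermis (11, 0.681) and autophagy (45, 0.374) lists had no member past the threshold and were not called, at the adjusted p given.

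In all, 237 probe sets were higher and 93 lower with hsp-6 RNAi (limma, adjusted p below 0.05), of which 208 and 63 changed more than 2-fold, and they stood for 195 and 69 genes. At an unadjusted p below 0.05 there were 2609, and rises were less in excess there, with 1377 higher and 1232 lower. The balance also moved with the fit: it was 613 higher and 436 lower with only these 2 groups in the fit, and 806 higher and 875 lower without the 2 outlying double RNAi arrays, a choice made after seeing the data. The 3 arrays of each group did not overlap for 39.7% of probe sets, against 10% by chance. They did not overlap for any gene named here as raised or lowered either. That is no added support, since these genes were chosen by their calls or by this lack of overlap. The total of 330 depended on single arrays. It was 132 without empty vector replicate 1 and 155 without replicate 3, and 97, 123 and 107 without hsp-6 RNAi replicates 1, 2 and 3. It was 739 without hsf-1 double RNAi replicate 3 and 204 without hsp-6;dve-1 replicate 1. Of 58 named calls 21 held without any 1 array. The others were lost 29, 19 and 29 at a time without empty vector replicates 1, 2 and 3, and 35, 34 and 31 without hsp-6 RNAi replicates 1, 2 and 3. Without hsf-1 double RNAi replicates 1 and 2, 9 and 8 were lost, and without hsp-6;dve-1 replicates 1, 2 and 3, 15, 1 and 8. None of the 17 of 35 lists that camera called held with an estimated correlation. The fry test, which asks whether the genes of a list move one way, called 4 of them, the heat shock, cytosolic ribosomal, glycolysis and superoxide dismutase lists.

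The heat shock genes that hsp-6 RNAi had raised were lower with added hsf-1 RNAi, beside the smaller loss of hsp-6 given above. hsf-1, as given above, was not called lower in these arrays. hsp-16.41 fell to 7.30 ± 1.62 (log2 change -5.70, SE 0.71, n = 3, adjusted p = 0.0051), hsp-16.2 by 5.65 (log2 change -5.65, adjusted p = 0.006) and hsp-70 by 5.50 (log2 change -5.50, SE 0.57, adjusted p = 0.0023). hsp-17 fell by 3.53 (log2 change -3.53, adjusted p = 0.026), while hsp-12.1, another small heat shock gene, rose by 1.60 (adjusted p = 0.029). The same arrays had far more transcript of sperm and cuticle genes, with msp-45, a major sperm protein gene, higher by 6.55 (SE 1.31, adjusted p = 0.022) and the collagen col-81 by 6.65 (SE 1.17, adjusted p = 0.016). The median change of all probe sets here was -0.10, which the changes given here are not corrected for.

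Of 23 heat shock genes 4 fell and 1 rose with hsp-6 and hsf-1 RNAi (7 down and 1 up adjusted over the list alone, median -0.33, adjusted p = 0.00693). With an estimated correlation the adjusted p = 0.504, and without hsf-1 double RNAi replicate 2 it was 0.0596. Of 49 sperm genes 33 rose and none fell (39 up adjusted over the list alone, median 4.66, adjusted p = 1.06e-20), and of 103 collagens 36 rose and 1 fell (74 up and 2 down adjusted over the list alone, median 2.00, adjusted p = 1.68e-28). Of 20 muscle genes 7 rose (15 adjusted over the list alone, median 1.33, adjusted p = 9.46e-10), among them troponin genes tni-1 by 2.36 and tnt-2 by 2.07. With an estimated correlation each of these 3 lists gave adjusted p = 0.522. Several major sperm protein genes read nearly alike. In hsf-1 double RNAi replicate 1, msp-45, msp-49, msp-50, msp-33 and msp-152 gave 12.7, 12, 12.13, 12.47 and 12.87. Whether their probe sets tell these genes apart was not tested, so the counts of sperm genes, here and below, need not be of separate genes. Of 23 oocyte and eggshell genes 1 fell (2 adjusted over the list alone, median -0.52, adjusted p = 2.74e-05; adjusted p = 0.878 with an estimated correlation). Of 20 intestine markers 4 rose (5 up and 1 down adjusted over the list alone, median 0.47, adjusted p = 0.00693), including the peptide transporter pept-1 by 3.31. Its adjusted p = 0.878 with an estimated correlation, and it was 0.268 without hsf-1 double RNAi replicate 3. No neuron gene of 32 passed (none adjusted over the list alone), though the list was called (median 0.44, adjusted p = 0.0346; adjusted p = 0.969 with an estimated correlation). That call was lost without hsp-6 RNAi replicate 2 (0.0551), and its direction turned without hsf-1 double RNAi replicate 3 (0.906).

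The collagen signal was uneven between the arrays of the group. Its median was 8.80 and 8.87 in hsf-1 double RNAi replicates 1 and 3 but 5.97 in replicate 2, against 4.96 to 5.24 with hsp-6 RNAi. The sperm median was above 8 in each of these 3 arrays, and ranged from 3.77 to 6.47 with hsp-6 RNAi and from 4.29 to 7.41 with empty vector. Replicate 3 and hsp-6;dve-1 replicate 2 lay farthest out on the first principal component, which held 56.5% of the variance. Without those 2 arrays, a choice made after seeing the data, 15 sperm genes (median 4.09), 19 collagens (median 1.74) and 5 muscle genes (median 0.97, list adjusted p = 1.37e-06) rose and 4 heat shock genes fell.

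**Figure D3:**
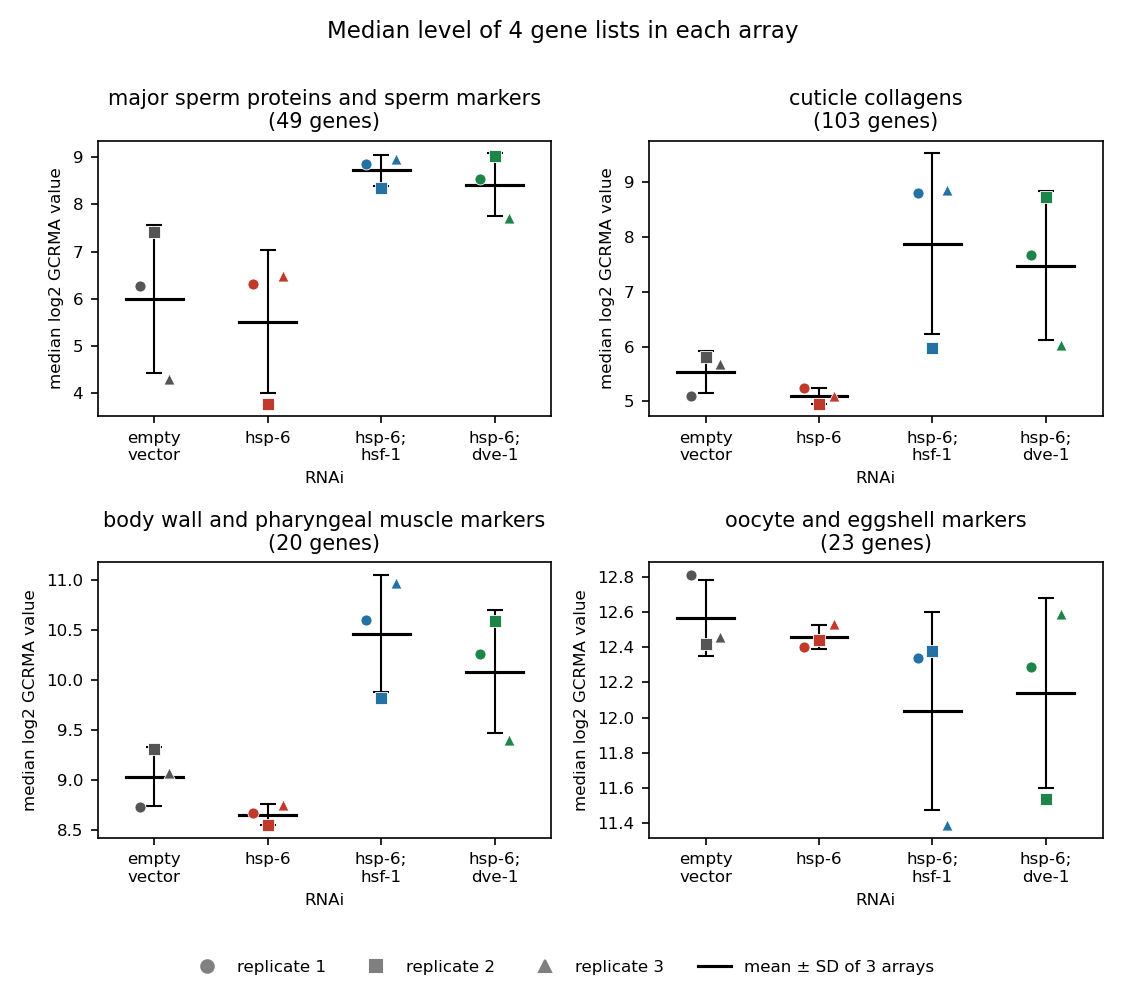
Median log2 GCRMA value (vertical axis) of the tested genes of the sperm, collagen, muscle and oocyte lists in each array of the 4 RNAi groups (horizontal axis), with 1 point per array and lines for the mean ± SD of 3 arrays. Sperm medians are highest in the 6 double RNAi arrays, while the collagen median reaches 8.87 in hsf-1 double RNAi replicate 3 and 5.97 in replicate 2.

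Single genes of fat metabolism moved both ways with hsp-6 and hsf-1 RNAi against hsp-6 RNAi. fat-5 fell by 1.80 (log2 change -1.80, SE 0.24, adjusted p = 0.006), fat-7, a stearoyl-CoA desaturase, by 2.32 (log2 change -2.32, adjusted p = 0.041) and ATP citrate lyase acly-1 by 0.88 (log2 change -0.88, adjusted p = 0.028). These were 3 of 20 fatty acid synthesis genes, 3 adjusted over the list alone, and the list was not called (adjusted p = 0.935, median 0.03, mean -0.09). Others rose: acdh-8 by 4.14 (adjusted p = 0.02) and kat-1 by 0.59 (adjusted p = 0.029), both of fatty acid oxidation, the lipid-binding lbp-7 by 2.44 (adjusted p = 0.041) and sphk-1 by 0.88 (adjusted p = 0.036). Their calls were lost without any of hsp-6 RNAi replicates 1 to 3 or hsf-1 double RNAi replicates 1 or 3 (up to 0.14). Those on kat-1, lbp-7 and sphk-1 were also lost without hsp-6;dve-1 replicate 1, that on lbp-7 without empty vector replicate 3 and that on sphk-1 without empty vector replicate 2. Among glycolytic and detoxification genes, ldh-1 fell by 1.51 (log2 change -1.51), aldo-1 by 1.29 (log2 change -1.29) and ugt-1 by 2.93 (log2 change -2.93, adjusted p = 0.006). Of 57 mitochondrial ribosomal genes 4 rose and none fell (7 up and 1 down adjusted over the list alone, median 0.18, adjusted p = 0.00161). They gave adjusted p = 0.96 with an estimated correlation, and 0.207 without hsf-1 double RNAi replicate 2. Of 67 respiratory chain genes 3 rose (3 adjusted over the list alone, median 0.22, adjusted p = 4.85e-05), with the cytochrome c gene cyc-2.2 at 4.89. No cytosolic ribosomal gene of 61 passed (none adjusted over the list alone), and their list was higher by a median of 0.09 (adjusted p = 0.000931). The last 2 lists gave adjusted p = 0.878 with an estimated correlation. In hsf-1 double RNAi replicates 1 to 3 acdh-8 read 7.06, 5.65 and 7.89, and cyc-2.2 read 7.97, 6.27 and 8.88. Both were lowest in replicate 2, as the collagen median was, so their rises are not separated from that uneven signal. The call on fat-5 held without any 1 array. Those on fat-7, ldh-1 and aldo-1 were lost without any of hsp-6 RNAi replicates 1 to 3 or hsf-1 double RNAi replicates 1 or 3, with adjusted p up to 0.15. The call on fat-7 was also lost without empty vector replicate 3 or hsp-6;dve-1 replicate 1, that on ldh-1 without empty vector replicate 2, and that on aldo-1 without any empty vector array or hsp-6;dve-1 replicate 1.

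In total 351 probe sets were higher and 333 lower with hsp-6 and hsf-1 RNAi than with hsp-6 RNAi (limma), 327 and 217 of them by more than 2-fold, standing for 268 and 252 genes. There were 2980 at an unadjusted p below 0.05, 1320 higher and 1660 lower, and arrays of the groups did not overlap for 34.4% of probe sets (10% by chance). The total of 684 was 48, 89 and 35 without hsp-6 RNAi replicates 1, 2 and 3. It was 35, 1433 and 165 without hsf-1 double RNAi replicates 1, 2 and 3, and 414 and 1104 without hsp-6;dve-1 replicates 1 and 2. Of 76 named calls 13 held without any 1 array, including hsp-70, hsp-16.41, hsp-16.2, rnh-1.3, fat-5 and ugt-1. Without empty vector replicates 1, 2 and 3, 8, 17 and 10 were lost, and without hsp-6 RNAi replicates 1, 2 and 3, 60, 56 and 62. Without hsf-1 double RNAi replicates 1, 2 and 3, 61, 4 and 46 were lost, sperm and collagen genes among them, and without hsp-6;dve-1 replicate 1, 21. The other 25 of 35 lists were not called, no call held with an estimated correlation, and fry called 4, the heat shock, collagen, sperm and muscle lists.

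In the arrays labelled hsp-6;dve-1, whose dve-1 signal was higher rather than lower, the same heat shock genes were also lower than with hsp-6 RNAi. hsp-16.2 fell by 4.48 (log2 change -4.48, SE 0.75, n = 3, adjusted p = 0.011), hsp-16.41 by 4.44 (log2 change -4.44, adjusted p = 0.009) and hsp-70, to 9.33 ± 0.29, by 3.59 (log2 change -3.59, SE 0.57, adjusted p = 0.0084). hsp-17 differed by -2.64 (adjusted p = 0.061), and hsp-12.1 rose by 1.93 (adjusted p = 0.015). The lectin clec-60 rose by 6.67 (SE 1.00, adjusted p = 0.0068), msp-45 by 5.95 (adjusted p = 0.028) and col-81 by 5.78 (adjusted p = 0.021). clec-60 was high with added hsf-1 RNAi too, at 9.98, 7.6 and 12.45 in replicates 1 to 3, against 3.58 to 4.51 with hsp-6 RNAi. The F-box gene fbxa-75 was at the table's minimum in every hsp-6 RNAi array and averaged 8.04 here, so its rise of 5.89 (adjusted p = 0.0028) is a lower bound. Its adjusted p pools the spread with that of arrays at the minimum, which show none, and may be too small.

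Of 23 heat shock genes 4 fell and 1 rose in the arrays labelled hsp-6;dve-1 (6 down and 1 up adjusted over the list alone, median -0.24, adjusted p = 0.0462; adjusted p = 0.764 with an estimated correlation). The list's call was lost without hsp-6 RNAi replicate 1 (0.0772) or 3 (0.0927) or hsp-6;dve-1 replicate 3 (0.173). Of 49 sperm genes 18 rose (36 adjusted over the list alone, median 3.78, adjusted p = 5.69e-16), of 103 collagens 27 rose (55 up and 2 down adjusted over the list alone, median 1.73, adjusted p = 1.1e-21), and of 20 muscle genes 6 rose (14 adjusted over the list alone, median 1.24, adjusted p = 8.16e-08). With an estimated correlation these lists gave adjusted p = 0.764. The collagen median was 7.68 and 8.73 in hsp-6;dve-1 replicates 1 and 2 and 6.03 in replicate 3. Without the 2 outlying arrays 2 sperm genes (median 2.99) and 9 collagens (median 1.35) rose. No oocyte gene of 23 passed (none adjusted over the list alone), and their list was lower (median -0.45, adjusted p = 0.000107). Of 5 yolk genes none passed, 4 were lower adjusted over the list alone, and the list was lower (median -0.36, adjusted p = 0.0461). The yolk call was lost without hsp-6 RNAi replicate 2 (0.208) or hsp-6;dve-1 replicate 1 (0.118) or 3 (0.0663). No neuron gene of 32 passed (none adjusted over the list alone), with a list median of 0.62 and adjusted p = 0.0278, or 0.673 without hsp-6;dve-1 replicate 2. These oocyte, yolk and neuron lists gave adjusted p = 0.947 with an estimated correlation.

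Of 57 mitochondrial ribosomal genes 9 rose and none fell in the arrays labelled hsp-6;dve-1 (15 adjusted over the list alone, median 0.28, adjusted p = 7.81e-06; adjusted p = 0.947 with an estimated correlation), with mrpl-12 at 1.45 and mrps-12 at 1.41. Of 67 respiratory chain genes 4 rose (7 up and 2 down adjusted over the list alone, median 0.24, adjusted p = 6.77e-05; adjusted p = 0.905 with an estimated correlation). No cytosolic ribosomal gene of 61 passed (none adjusted over the list alone), with a list median of 0.10 and adjusted p = 0.000697, or adjusted p = 0.947 with an estimated correlation. fat-5 fell by 2.32 (log2 change -2.32, SE 0.24, adjusted p = 0.00095) and acly-1 by 1.12 (log2 change -1.12, adjusted p = 0.011), 2 of 20 fatty acid synthesis genes (3 adjusted over the list alone, list adjusted p = 0.289, median 0.04, mean -0.25). hrg-9 fell by 3.01 (log2 change -3.01, adjusted p = 0.029), and was the 1 of 13 genes of the mitochondrial unfolded protein response list past the threshold (list adjusted p = 0.309). Of 61 C-type lectins 5 rose, among them clec-52 by 5.07 (adjusted p = 0.0028), and 5 fell (list adjusted p = 0.815).

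In total 335 probe sets were higher and 357 lower in the arrays labelled hsp-6;dve-1 than with hsp-6 RNAi (limma), 300 and 234 by more than 2-fold, standing for 274 and 251 genes. There were 2918 at an unadjusted p below 0.05, 1300 higher and 1618 lower, and arrays did not overlap for 33.8% of probe sets (10% by chance). The total of 692 was 101, 183 and 102 without hsp-6 RNAi replicates 1, 2 and 3. It was 134, 221 and 1242 without hsp-6;dve-1 replicates 1, 2 and 3, and 1047 without hsf-1 double RNAi replicate 3. Of 70 named calls 19 held without any 1 array, including hsp-70, hsp-16.41, fat-5, clec-60, clec-52 and fbxa-75. That on hsp-16.2 was lost without hsp-6 RNAi replicate 1 or 3 or hsp-6;dve-1 replicate 1 (adjusted p up to 0.055), and those on msp-45, col-81 and hrg-9 without hsp-6 RNAi replicates 1, 2 or 3 or hsp-6;dve-1 replicates 1 or 2 (up to 0.11). Among the 70, 8, 8 and 2 were lost without empty vector replicates 1, 2 and 3, 49, 40 and 47 without hsp-6 RNAi replicates 1, 2 and 3, and 7 and 2 without hsf-1 double RNAi replicates 1 and 2. Without hsp-6;dve-1 replicates 1, 2 and 3, 45, 36 and 2 were lost. The other 25 of 35 lists were not called by camera, and none was called with an estimated correlation or by fry.

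Many probe sets that responded to hsp-6 RNAi moved back in both double RNAi groups, though which share did so depended on single arrays. Of the 237 probe sets that hsp-6 RNAi raised, 134 were lower with added hsf-1 RNAi and 107 in the arrays labelled hsp-6;dve-1, and 97 were lower in both, hsp-70, hsp-16.41 and hsp-16.2 among them. A further 37 passed only with hsf-1, including hsp-17, and 10 only in the arrays labelled hsp-6;dve-1, including hrg-9. When the difference between the double RNAi groups was itself tested, 1 probe set of these classes differed. Of the 93 lowered probe sets, 32 were higher with added hsf-1 RNAi, 41 in the arrays labelled hsp-6;dve-1 and 29 in both, mrps-21 and hsp-6 itself among them, and none of those past the threshold in only 1 group differed between the groups. Between the double RNAi groups, 219 of 351 and 335 higher probe sets and 229 of 333 and 357 lower ones were shared, and none was opposite.

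These comparisons share the hsp-6 RNAi arrays. In 100 simulations without any effect and with independent noise, the changes of the double RNAi groups had a mean covariance of 0.0804 across probe sets. The observed value was 0.829 (correlation 0.501 against 0.914, and probe sets are not independent replicates). The changes with hsp-6 RNAi and with added hsf-1 RNAi had a covariance of -0.252, against -0.08 simulated. Their correlation was -0.387, against -0.499, so the shared arrays alone give a negative one. For the arrays labelled hsp-6;dve-1 the covariance was -0.248 against -0.0804, and the correlation -0.397 against -0.501. Simulations that kept the hsp-6 RNAi change, with no effect of the added RNAi, gave a correlation of -0.257 for each group. The change they kept is the measured one and holds its noise. The overlaps counted above averaged at most 0.01 without any effect, where almost nothing is called, so an overlap near 0 was fixed in advance. They averaged at most 0.03 with the hsp-6 RNAi change kept. Both sets of simulations leave out variation shared by genes. Of the raised probe sets that moved back in either group, 67.4% did so in both (97 of 144). This was a minority without hsf-1 double RNAi replicate 1 (23.2%) or 3 (40.1%), without hsp-6;dve-1 replicate 1 (36.8%) or 2 (41.3%), and with only the compared groups in the fit (46.4%). Of the lowered probe sets 65.9% did so in both (29 of 44), but 46.2% and 37.5% without hsp-6 RNAi replicates 2 and 3, 16% and 33.3% without hsf-1 double RNAi replicates 1 and 3, 33.3% with only the compared groups in the fit, and 22.2% with hsp-6 RNAi replicates 1 and 3 averaged. The counts also followed single arrays. The 134 became 66 and 76 without empty vector replicates 1 and 3, 21, 44 and 19 without hsp-6 RNAi replicates 1, 2 and 3, 24 without hsf-1 double RNAi replicate 1, and 87 without hsp-6;dve-1 replicate 1. The 107 became 62 without empty vector replicate 1, 27, 43 and 28 without hsp-6 RNAi replicates 1, 2 and 3, 179 without hsf-1 double RNAi replicate 3, and 32 and 67 without hsp-6;dve-1 replicates 1 and 2. The 97 became 55 and 63 without empty vector replicates 1 and 3, 19, 35 and 17 without hsp-6 RNAi replicates 1, 2 and 3, 23 without hsf-1 double RNAi replicate 1, and 32 and 64 without hsp-6;dve-1 replicates 1 and 2. The 32 became 18 and 20 without empty vector replicates 2 and 3, 6, 6 and 3 without hsp-6 RNAi replicates 1, 2 and 3, 4 without hsf-1 double RNAi replicate 1 and 18 without hsp-6;dve-1 replicate 1. The 41 became 21 and 22 without empty vector replicates 2 and 3, 8, 13 and 8 without hsp-6 RNAi replicates 1, 2 and 3, 25 and 95 without hsf-1 double RNAi replicates 1 and 3, and 11 without hsp-6;dve-1 replicate 1. The 29 became 17 without empty vector replicate 2, 6, 6 and 3 without hsp-6 RNAi replicates 1, 2 and 3, 4 without hsf-1 double RNAi replicate 1 and 11 without hsp-6;dve-1 replicate 1.

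Compared directly, the double RNAi groups differed in 28 probe sets, 27 higher and 1 lower in the arrays labelled hsp-6;dve-1 (limma; 277 at an unadjusted p below 0.05; arrays did not overlap for 3.7%, against 10% by chance). fbxa-75 was higher there by 5.88 (log2 hsf-1 double RNAi minus hsp-6;dve-1, -5.88, SE 0.76, n = 3, adjusted p = 0.0086), and the glutathione transferase gst-39 by 3.96 (-3.96, SE 0.49, adjusted p = 0.006). pals-11 (-4.53, adjusted p = 0.039) and pals-5 (-4.36, adjusted p = 0.039), genes known to respond to intracellular infection, were higher as well. pals-11 was at the table's minimum in every array of the other groups, so its difference is a lower bound. fbxa-75 read 7.68, 6.13 and 10.32 in the arrays labelled hsp-6;dve-1 and 2.16 or 2.17 in all others. The p-values pool the spread over all 12 arrays, and arrays at the minimum show none. The SE of fbxa-75 and of pals-11 may thus be too small. With only these 2 groups in the fit, 1 of the 28 calls remained. The lectins clec-52 (-4.41, adjusted p = 0.02) and clec-5 (-2.17, adjusted p = 0.006) were higher too, and Y47H10A.5 was lower (1.92, adjusted p = 0.029). hsp-70 differed by -1.91 (adjusted p = 0.81) between these groups. Of the named calls, those on F57G4.11, gst-39, K07G5.4 and clec-5 held without any 1 array. That on fbxa-75 was lost without hsf-1 double RNAi replicate 1 (0.056), and those on pals-5 and pals-11 without any 1 of the empty vector, hsp-6 RNAi or hsf-1 double RNAi arrays (up to 0.18), and pals-11 also without hsp-6;dve-1 replicate 2. That on clec-52 was lost without replicate 1 or 2 of either double RNAi group (up to 0.12), and that on Y47H10A.5 without any array except empty vector replicate 3, hsp-6 RNAi replicate 2 and hsp-6;dve-1 replicate 3 (up to 0.091). The count was 16 without empty vector replicate 2, 15 without hsp-6 RNAi replicate 1 or 3, 11 and 14 without hsf-1 double RNAi replicates 1 and 2, and 18 and 17 without hsp-6;dve-1 replicates 1 and 2. Camera called 16 of 35 lists between these groups, 12 higher and 4 lower with hsf-1 RNAi, but 5 without hsf-1 double RNAi replicate 3 and 5 without hsp-6;dve-1 replicate 3. None was called with an estimated correlation or by fry.

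**Figure D4:**
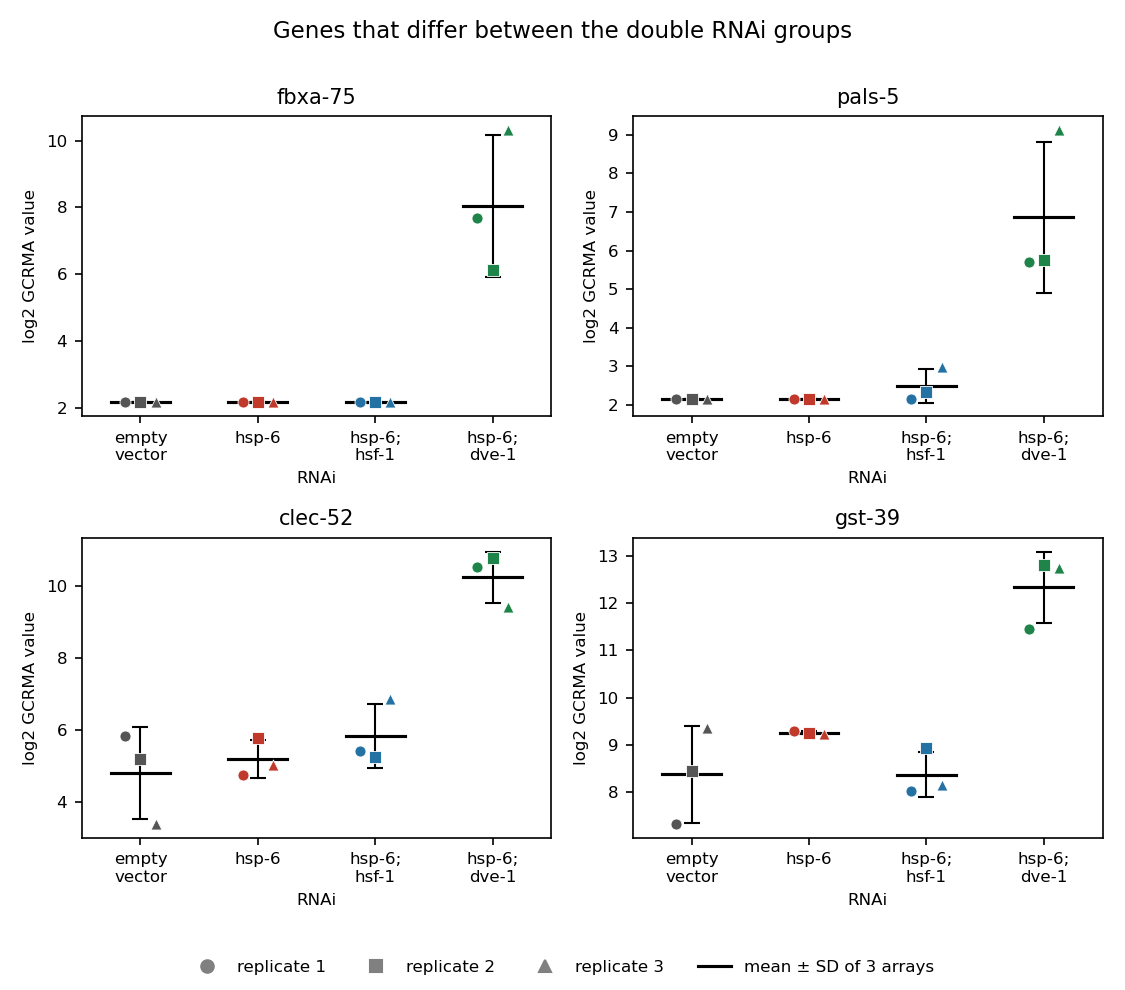
Log2 GCRMA value (vertical axis) of fbxa-75, pals-5, clec-52 and gst-39 in the 4 RNAi groups (horizontal axis), with 1 point per array and lines for the mean ± SD of 3 arrays. For fbxa-75 the 3 arrays labelled hsp-6;dve-1 average 8.04, while all other arrays sit at 2.16 or 2.17, at or next to the table's minimum.

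Against empty vector, hsp-6 with hsf-1 RNAi left hsp-70 at 0.95 (SE 0.57, adjusted p = 0.26) and hsp-16.41 at 0.02 (adjusted p = 0.99), while hsp-70 in the arrays labelled hsp-6;dve-1 was raised by 2.87 (SE 0.57, adjusted p = 0.035). In the same arrays aldo-1 was raised by 2.00 (adjusted p = 0.018), clec-60 by 7.46 (adjusted p = 0.0064) and gst-39 by 3.95 (adjusted p = 0.0037), and hsp-6 was lower (2.46-fold, adjusted p = 0.05). The calls on clec-60 and gst-39 held without any 1 array. Those on hsp-70 and hsp-6 were lost without any 1 of the empty vector or hsp-6 RNAi arrays or hsp-6;dve-1 replicate 1 or 2 (adjusted p up to 0.12 and 0.17), and that on hsp-6 also without hsf-1 double RNAi replicate 1 (0.054). The call on aldo-1 was lost without empty vector replicate 1 or 3 or hsp-6;dve-1 replicate 2 (up to 0.074). No probe set passed for hsp-6 with hsf-1 RNAi (limma; 3593 at an unadjusted p below 0.05, smallest adjusted p = 0.073), and 211 were higher and 63 lower in the arrays labelled hsp-6;dve-1, with 1615 higher and 1619 lower at an unadjusted p below 0.05. Of the 35 lists camera called 20 for hsp-6 with hsf-1 RNAi (12 higher, 8 lower; 17 to 21 with 1 array left out) and 18 for the arrays labelled hsp-6;dve-1 (11 higher, 7 lower; 14 to 19 with 1 array left out). None was called with an estimated correlation, and fry called none for the former and 1 for the latter, the lysozyme, saposin-like and antimicrobial peptide list. The count of 0 became 1 without empty vector replicate 3, hsf-1 double RNAi replicate 1 or hsp-6;dve-1 replicate 1, 1047 without hsf-1 double RNAi replicate 2, and 316 and 230 without hsp-6;dve-1 replicates 2 and 3. The count of 274 became 46 and 43 without empty vector replicates 1 and 3, 71, 132 and 74 without hsp-6 RNAi replicates 1, 2 and 3, 900 without hsf-1 double RNAi replicate 3, 57.7% of 274 without its replicate 1, and 108, 61 and 1038 without hsp-6;dve-1 replicates 1, 2 and 3.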

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

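The tests of a weaker knockdown, of dilution, of larvae, of males and of differing amounts of material were chosen only after the result was seen, and the intracellular pathogen list was written after it.

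Heat shock genes were lower in both double RNAi groups than with hsp-6 RNAi, and dilution by RNA of other animals is argued against as the whole cause, since oocyte and eggshell transcripts fell by a median of at most 0.52 on the log2 scale (-0.52), against medians of -5.58 and -4.01 for the 4 heat shock genes called with hsp-6 RNAi against empty vector, of which hsp-17 was not called lower in the arrays labelled hsp-6;dve-1 (adjusted p = 0.061). A weaker hsp-6 knockdown may account for part of it, because both hsp-6 probe sets were higher than with hsp-6 RNAi alone, by at least 1.99. The hsp-6 RNAi effect retained with added hsf-1 RNAi had a median of 7.5% in the 4 heat shock genes, 29.1% in the 191 other raised genes, 31.6% in 68 other lowered genes and 41.9% in hsp-6, and in the arrays labelled hsp-6;dve-1 31.5%, 37.6%, 21.8% and 36.5%, with wide quartiles (7.1% and 52.7% for the other raised genes with hsf-1 RNAi) whose range overlapped between the heat shock and the other raised genes in both groups. A requirement for hsf-1 beyond what both groups share cannot be told apart from that, with adjusted p = 0.645 for the heat shock list between the double RNAi groups with an estimated correlation (0.0234 with the preset 0.01, median -0.17, and 0 of 23 genes called by limma). Without the 2 outlying arrays, a choice made after seeing the data, that list gave 3.98e-05 with the preset and 0.395 with an estimated correlation, and hsp-16.2 was lower by a log2 change of -1.72 (adjusted p = 0.035).

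Sperm and collagen genes were higher in both double RNAi groups. Larvae, which the washes should remove, stay open for the collagens: 16 moulting genes had medians of 0.88 and 0.69, with a larger camera p of 0.0771, so the test was not met in both groups. For the sperm genes, 2 double RNAi arrays had a sperm median above every hsp-6 RNAi array without a moulting median above them, which speaks against larvae there but does not exclude them, since the moulting median was already 5.04 to 5.41 with hsp-6 RNAi and could hide a small share. Males cannot be told apart either, because only 2 genes of the male soma list were measured. No test could decide whether the change is a biological effect of the added RNAi, which may also act on the germline or cuticle.

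For the 27 of 28 differing probe sets that were higher in the arrays labelled hsp-6;dve-1, more sperm material in those arrays is argued against, since the highest of their sperm list medians lay only 0.69 above the lowest of the hsf-1 double RNAi arrays, while each of the 27 differed by 1.63 or more. More larval material cannot be decided on, because the collagen median was used to gauge it and a larval origin of the collagens stays open, as given above. In 6 of the 9 pairs of an hsp-6;dve-1 and an hsf-1 double RNAi array the collagen median was lower in the former. The log2 difference was -2.84 to -1.12 in 4 of them, and -0.07 and -0.14 in the 2 with hsp-6;dve-1 replicate 2. Each of the 27 was higher in all 9. These pairs cross 3 arrays with 3, so they are not separate observations. In the pairs with the most alike residuals the collagen difference was -1.12 (replicate 1 of each group) and 0.06 (hsp-6;dve-1 replicate 3, hsf-1 replicate 2). It was -0.14 for hsp-6;dve-1 replicate 2 and hsf-1 replicate 3, so the collagens were not clearly higher in any of these pairs. A candidate explanation is a response to an intracellular pathogen or a like state in those arrays: the 20 tested list members outside the 28 were higher as a list (median 1.52, camera p = 6.04e-24, and p = 0.0109 with an estimated correlation). None of the 20 passed alone (limma, smallest adjusted p = 0.17), with 11 at an unadjusted p below 0.05. Their differences ran from 0.03 to 3.65. Among the arrays labelled hsp-6;dve-1, all of them but pals-22 were highest in replicate 3. F26F2.4 read 4.2, 5.53 and 10.71 in replicates 1 to 3, and pals-31 read 6.23, 6.59 and 7.07. The list was not tried without replicate 3, so how far it rests on that array is open. Whether such a response came with the RNAi or from an infection was not tested, and 3 of the list are among the 28.

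The count of 28 arose from a test of the difference between the groups. Its named members, as log2 hsf-1 double RNAi minus the arrays labelled hsp-6;dve-1, are fbxa-75 at -5.88, pals-11 at -4.53, clec-52 at -4.41, pals-5 at -4.36, F57G4.11 at -4.14, F42C5.3 at -3.97, gst-39 at -3.96, K07G5.4 at -3.58, clec-5 at -2.17 and Y47H10A.5 at 1.92. Among the control probe sets, which the comparisons do not use, 3 were higher with hsp-6 RNAi than with empty vector. They were Gapdh 5' by 1.26, Gapdh M by 1.01 and another control (r2) by 0.77. The sources used here do not say what that other control detects. These 3 were also higher in the hsf-1 double RNAi arrays than with empty vector, by 0.99, 0.71 and 0.47. Several other controls were lower there, such as BioB-5 by a log2 change of -0.57, CreX-5 by -0.56 and P1-cre-3 by -0.49. The comparison of these groups, in which no tested probe set passed, was not corrected for such shifts. Their cause was not tested. The 3' minus 5' difference of Gapdh, which can reflect RNA quality, was 0.37 to 0.82 with empty vector and 0.06 to 0.15 with hsp-6 RNAi. That of actin was 1.81 to 2.03 with empty vector, 1.79 to 2.09 with hsp-6 RNAi and 1.12 to 1.77 in the double RNAi arrays. In the latter Gapdh gave 0.04 to 0.25. That of ubiquitin differed little, at 3.00 to 3.26 with empty vector, 3.075 to 3.19 with hsp-6 RNAi and 3.23 to 3.37 in the double RNAi arrays. A difference in RNA quality is thus not separated from the groups by Gapdh and actin, and ubiquitin does not show one.

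Each comparison's 6 arrays can be split in only 10 ways, so no share of splits can fall under 0.05. The real split called 330 probe sets for hsp-6 RNAi against empty vector, 684 and 692 for the double RNAi groups against hsp-6 RNAi and 274 for the arrays labelled hsp-6;dve-1 against empty vector, and the highest other split called 0 in each, so that 1 of 10 splits was as large. For hsp-6 with hsf-1 RNAi against empty vector all 10 splits called 0 (limma; 3593 probe sets at an unadjusted p below 0.05 in the real split). Between the double RNAi groups 2 of 10 splits called at least the real 28. The highest other called 687, and set hsf-1 double RNAi replicates 1 and 3 and hsp-6;dve-1 replicate 2 against the rest, which points to a structure of the samples, as in the collagen medians of 8.80, 8.87 and 8.73 in those arrays.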

How the results depend on the processing

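The fits with hsp-6 RNAi replicates 1 and 3 averaged and without the 2 outlying double RNAi arrays were chosen after seeing the data. The named genes past the threshold kept their direction under every alternative run, though 1303 of 4862 values were no longer past it. Their arrays did not overlap between the groups, so most alternatives, such as leaving out 1 array, could not turn a direction. The kept directions are therefore no added support. The lists were tried under alternatives in 3 comparisons, hsp-6 RNAi against empty vector and each double RNAi group against hsp-6 RNAi. Of 407 values of the 37 lists called there, 310 stayed called in the same direction, 95 were no longer called and 2 reversed. Another quantile normalization, centring on array medians and robust fitting left every count within 1.5 times. Signal over background limits the genes near the table's minimum, such as fbxa-75, whose changes are lower bounds. With independent noise, the self-test recovered most changes of 2 and few of 1 on the log2 scale.

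Counts are given in the order higher, lower. With only the compared groups in the fit, hsp-6 RNAi against empty vector gave 613 and 436, the hsf-1 double RNAi group against hsp-6 RNAi 176 lower, and the arrays labelled hsp-6;dve-1 against hsp-6 RNAi 220 and 213. Between the double RNAi groups 1 remained called, the latter arrays against empty vector gave 36, and 13 lowered probe sets were higher in both. With replicates 1 and 3 averaged, these comparisons gave 80 and 22, 10 and 25, 55 and 51, 15, and 74. The overlaps became 20, 28 and 18 of the raised and 2, 9 and 2 of the lowered probe sets (hsf-1, dve-1, both), which goes with 1 array fewer. Without the outlying arrays hsp-6 RNAi gave 806 and 875, with all 330 calls above among them, and the overlaps became 247, 241 and 189, and 145, 171 and 123. With the replicate number as a block, hsp-6 RNAi gave 53 lower, the double RNAi groups 164 and 163, and 175 and 209, and 15 between them, with 149 against empty vector and 18, 19 and 13 of the lowered. Same-number arrays had residual correlations from -0.761 to 0.614, and 8 of 18 such pairs were over 0.1. Double RNAi arrays also matched under other numbers. hsf-1 replicate 2 and hsp-6;dve-1 replicate 3 gave 0.846, and hsf-1 replicate 3 and hsp-6;dve-1 replicate 2 gave 0.839. Their same-number pairs gave -0.739 for replicate 2 and -0.761 for replicate 3. The block does not follow this structure, and no fit between the double RNAi groups took it into account. Without a filter the hsf-1 double RNAi group gave 49 and 174, the arrays labelled hsp-6;dve-1 122 higher, 17 between them, 4 and 83 against empty vector, and 18 of the lowered with hsf-1 and 18 with both. The 28 became 6 with the stricter minimum, which tests fewer probe sets, and 16 with low values set to log2 4, and the 0 became 1 without the trend. The rise of dve-1 lost its call without a filter (2.53, adjusted p = 0.088), with the block (2.53, 0.064), with replicates averaged (2.46, 0.099) and in the other probe set (0.24, 0.63). Except where stated, the cause was not tested.

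Leaving out 1 array gave 78 to 428 and 19 to 311 for hsp-6 RNAi, 10 to 821 and 24 to 612 for the hsf-1 double RNAi group, and 52 to 679 and 49 to 563 for the arrays labelled hsp-6;dve-1. It gave 11 to 25 between these groups, and 0 to 1047 and 43 to 1038 against empty vector. The overlaps ran from 19 to 152, 27 to 179 and 17 to 109 of the raised, and 3 to 44, 8 to 95 and 3 to 32 of the lowered. hsp-6 ran from -4.36 to -4.16, hsf-1 from -1.06 to -0.78 and dve-1 from 2.11 to 2.99.

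The reversed values were of results without a call except for the neuron list. That list in the hsf-1 double RNAi group gave adjusted p = 0.954 without the outlying arrays, and 0.000207 to 0.906, the latter without its replicate 3, with 1 array left out. With hsp-6 RNAi, dve-1 gave -0.10 after another quantile normalization, and -0.05 and -0.13 without hsp-6 RNAi replicates 1 and 2. pod-2 gave -0.08 without empty vector replicate 2 and -0.01 without hsp-6 RNAi replicate 1 (up to 0.11 with 1 array left out), and with added hsf-1 RNAi 0.02 without replicate 1 (down to -0.44). hsf-1 in the arrays labelled hsp-6;dve-1 gave 0.25 without their replicate 2 (down to -0.37) and 0.25 without the outlying arrays. Between the double RNAi groups hsp-6 gave 0.04 without hsp-6;dve-1 replicate 1 (down to -0.53), hsp-60 -0.21, -0.09 and -0.17 without hsf-1 replicates 1 and 2 and hsp-6;dve-1 replicate 2 (up to 0.3), and fasn-1 0 without hsp-6;dve-1 replicate 1 (down to -0.16).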

Other observations

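Defence genes moved both ways in the double RNAi groups. With added hsf-1 RNAi 4 of 52 lysozyme, saposin-like and antimicrobial peptide genes rose and 5 fell against hsp-6 RNAi (6 and 9 adjusted over the list alone, camera adjusted p = 0.789). The antimicrobial peptide gene nlp-33 rose by 2.57 (adjusted p = 0.006), a call that held without any 1 array. In the arrays labelled hsp-6;dve-1, 6 of these genes rose and 2 fell (7 and 7 adjusted over the list alone, camera adjusted p = 0.139), with lys-6 up by 5.18 (adjusted p = 0.016) and spp-4 by 4.56 (adjusted p = 0.01). The call on lys-6 was lost without hsp-6 RNAi replicate 1, 2 or 3 or hsp-6;dve-1 replicate 1 or 2 (adjusted p up to 0.073), and that on spp-4 without hsp-6 RNAi replicate 1 or 3 (up to 0.055).

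Of 23 tested intracellular pathogen response genes, a list written after the data had been seen, 11 rose in the arrays labelled hsp-6;dve-1 against hsp-6 RNAi (15 adjusted over the list alone, median 3.33). The camera p of this list was 1.57e-11, with a p of 0.0766 where the correlation was estimated. Among the arrays labelled hsp-6;dve-1, replicate 3 was highest for every tested member except pals-22, and the list was not tried without it. With added hsf-1 RNAi none passed (limma, none adjusted over the list alone), with a median of 0.30 and a camera p of 0.131. The list includes fbxa-75, pals-11 and pals-5, which are among the 28 probe sets that differ between the double RNAi groups and were seen before the list was written.

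All 6 double RNAi arrays were closest to an array of the other double RNAi group.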
